A study of Xenopus laevis with 9 samples.

How the data were processed

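Whole Xenopus laevis embryos, in dishes of 25, were exposed from stage 7 to stage 18 to 1e-06 M TTNPB, 1e-06 M AGN193109 or 0.1% ethanol. There were 27 dishes, 3 for each treatment and female; the labels call the dishes technical and the 3 females biological replicates. The deposited table holds 9 arrays, 1 per female and treatment, and how the dishes were combined into arrays is not given in the sources used here. Samples were grouped by the treatment and the female that their titles name. Per the labels' protocols, 5 Bacillus RNAs were added to each homogenate in proportion to its DNA, and the authors converted the array signal to mRNA copies per cell with these spikes (the Percellome method); the submitters' processing notes name MAS5, without a version. The deposited signal is on a linear scale, from 0 to 531 copies per cell, with 1 value of 0, and its error includes 1 scaling factor per array that is shared by all probe sets. The authors' deposited comparison table gives a signed fold score per probe set, which equalled the ratio of the group means within 1% for 100% of the 15610 probe sets, and an unadjusted p-value for each ligand against vehicle, whose test the deposited file does not state. Another 9 columns of per-sample values were not used.

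Of 15610 probe sets, 120 array controls were left out of the tests. Through the platform annotation, with symbols updated from a table of gene names, 9303 of the other 15490 probe sets had 1 gene, 195 several and 5992 none; 9226 gene identifiers were matched, and no gene was named from a probe set with several. L and S at the end of a symbol mark the copies of a gene on the 2 subgenomes. A pseudocount of 2.43 copies per cell (the 20th percentile of all values) was added before log2, so that changes of low genes are understated, and a probe set was tested if at least 3 of the 9 arrays lay above the 30th percentile (4.00 copies per cell), which left 11325. Limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend) was fitted to all 9 arrays with the treatment and the female as a block, leaving 4 residual degrees of freedom; tests were two-sided, with Benjamini-Hochberg adjustment within each contrast and calls at an adjusted p below 0.05. The design, the alternatives, the gene lists and the rule for naming genes were set before the data were examined, except the alternatives that are said to have been added. The block follows the labels, which give every female's clutch all 3 treatments. Arrays of the same female also deviated together, with correlations of their deviations from the group means from 0.498 to 0.620 in all 9 pairs, against -0.376 to -0.183 in the 18 pairs of different females. Deviations from a group mean cancel over the 3 females, so positive values within females force negative ones between them on average. The block removes differences in level between the 3 clutches, so p-values rest on how the treatment changes varied from clutch to clutch. In the fit to the deposited values this spread was taken from its trend over all probe sets, as described below.

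In the fit to the deposited values the prior degrees of freedom were infinite, so that every variance was taken from the trend alone, and its smallest p-values are not read as probabilities here. After median centring the prior degrees of freedom were 11.9, and after quantile normalization 7.77. Adjusted p-values after median centring are given wherever they end a gene's call that is described in the results.

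The 31 fixed gene lists covered retinoic acid metabolism and transport, retinoid receptors and cofactors, Hox paralog groups 1 to 5, 6 to 8 and 9 to 13, hindbrain and Hox cofactors, caudal progenitors and presomitic mesoderm, somites, skeletal muscle, forebrain and eye, midbrain, cement gland and hatching gland, neural crest, placodes, primary neurogenesis, neural plate progenitors, heart, blood and vessels, pronephros, endoderm, notochord and floor plate, epidermis, multiciliated cells and ionocytes, the FGF, Wnt, BMP and Notch pathways, the cell cycle, stress and apoptosis, housekeeping references and ribosomal proteins. L and S copies counted as separate members, and the probe set with the highest mean stood for a gene. Lists were tested with camera at a preset correlation of 0.01, with adjustment over the lists of a contrast, and again with an estimated correlation and with fry. Camera called 14 lists under TTNPB (8 up), 10 under AGN193109 (1 up) and 16 between the ligands (9 up); with an estimated correlation it called 3 (Hox groups 1 to 5, forebrain and eye, and cement gland and hatching gland), 0 and 2, and 4, 2 and 4 lists had an unadjusted p below 0.05.

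Genes were named by a fixed rule: per contrast, the 12 largest rises and the 12 largest falls among called genes with the same direction in all 3 females, up to 2 called members in each direction from every list that was called or had at least 3 called members, and a fixed set of developmental genes whether called or not. The genes rarb, hoxb1, hoxd1, hoxd4, ripply2, actc1 and etv3l of that set were among those not matched to a probe set with 1 gene, and hoxa13 and egr2 lay below the filter. Of the genes named, eps8l3.S, gpx1.S and adsl.L, and the gene copies compared in the last part, were chosen after their values were seen. Some genes named under 1 contrast were also given under another, and not every named gene is described.

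The procedure was tested on simulated data with known answers, 30 simulations of 11325 probe sets with 200 changed under TTNPB. Changes of 1.25-fold were recovered in 64.3% of cases for TTNPB against vehicle, 1.5-fold in 99.5%, and 2-fold and 4-fold in 100%, and 6.80% of the calls were false. When a shift common to all probe sets of an array was added (SD 0.0794 on the log2 scale), false calls without centring reached 214 in 1 simulation for TTNPB against vehicle (10.4% of the calls of all 30) and 883 between the ligands (27.2%). After median centring they were at most 21 and 19. With this shift, changes of 1.25-fold for TTNPB against vehicle were recovered in 36.5% of cases without centring and in 64.1% after median centring. The list of ribosomal proteins, the largest with 72 tested members, was called in 30 of 30 simulations when shifted by 0.5 on the log2 scale, with the preset and with the estimated correlation. Smaller lists were not simulated. The noise in the list simulations was independent between probe sets, so they could not test the choice between the preset and the estimated correlation. The alternatives were median centring, quantile normalization, pseudocounts of 0.525 and 6.04 copies per cell (the 5th and the 40th percentile), no filter, a filter at the 50th percentile, no replicate block, only the 6 arrays of a contrast, no trend, array weights, 1 probe set per gene, thresholds of 0.1 and 0.01, and each female and each array left out in turn. Counting numbered copies of a gene, such as gbx2.1, as members of its list was an alternative added after the data were examined.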

Results

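Messenger RNA was measured on Affymetrix arrays in whole Xenopus laevis embryos. The embryos developed from Nieuwkoop and Faber stage 7, before gastrulation, to stage 18, in neurulation, in the presence of a retinoid ligand or of its solvent. TTNPB is a synthetic agonist of the retinoic acid receptors. AGN193109 is, per the labels, an inverse agonist or antagonist of these receptors. Each ligand was given at 1e-06 M, and the vehicle was 0.1% ethanol. The fertilised eggs of 3 females, A, F and G, were each divided among the 3 treatments, which gave 9 arrays, 1 per female and treatment. The deposited values are mRNA copies per cell. Levels are given as mean ± SD over the 3 females (n = 3). Of 15490 probe sets that are not array controls, 11325 were tested, and 7405 of these belonged to 1 named gene.

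The summed copies per cell ranged from 294086 to 347765 per array, and the median of all probe sets from 7.61 to 9.56. The sums averaged 309546 ± 24029 under vehicle, 329285 ± 10371 under TTNPB and 333031 ± 16497 under AGN193109. Within females, the log2 sum was higher under TTNPB by 0.09 ± 0.121 (SD), in 2 of 3 females (exact two-sided sign-flip permutation, p = 0.5). It was higher under AGN193109 by 0.11 ± 0.0666, in 3 of 3 females (exact p = 0.25). Between TTNPB and AGN193109 it differed by -0.02 ± 0.061 (exact p = 1). The smallest p that 3 females allow is 0.25. Median centring of the arrays removed a log2 shift of 0.11 from the TTNPB comparison, 0.13 from the AGN193109 comparison and -0.01 from that of the ligands. Changes of single genes and list medians are therefore given relative to the array median, as log2 change ± SE, unless stated. Calls and adjusted p-values come from the values as deposited unless stated. For gene lists, counts joined by "and" give higher members first, and the counts after median centring follow where the share of rises moved by over 10 percentage points. Where limma called 0 and 0 members after centring, the counts at an unadjusted p below 0.05 follow. The number of arrays limits the precision of every value.

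The first comparison asked which transcripts differ when the retinoic acid receptors are activated from before gastrulation. TTNPB raised both copies of cyp26a1 and all 7 measured Hox genes of paralog groups 1 to 5. It lowered 19 of 26 measured genes of the forebrain and eye and 8 of 10 of the cement gland and hatching gland. The retinoic acid hydroxylase gene cyp26a1.S rose most, from 18.5 ± 2.15 to 167 ± 11.1 copies per cell (log2 change 2.91 ± 0.064; 3.02 as deposited). Its copy cyp26a1.L went from 24.2 ± 3.84 to 165 ± 12 copies per cell (2.55 ± 0.08). The astacin protease gene astl3a.1.L, of the hatching gland list, fell most, from 18.6 ± 2.99 to 0.344 ± 0.0659 copies per cell (-3.03 ± 0.16; -2.91 as deposited).

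Among the largest rises was that of dhrs3.L, a retinaldehyde reductase gene (2.05 ± 0.07). Rises also occurred in pik3r5.S, for a regulatory subunit of phosphoinositide 3-kinase (1.79 ± 0.11), and in dusp6.L, for a phosphatase of ERK (1.36 ± 0.071). The Hox genes hoxb5.S (1.71 ± 0.12), hoxb4.S (1.45 ± 0.071), hoxc5.L (1.35 ± 0.12) and hoxa3.S (1.3 ± 0.10) rose. So did aldh18a1.L (1.29 ± 0.11), an enzyme gene of proline synthesis, the transcription factor gene gata3.S (1.2 ± 0.098) and the semaphorin gene sema3fl.S (1.05 ± 0.14). Large falls were those of xa-1.L (-2.86 ± 0.093) and crisp1.5.S (-2.73 ± 0.095). The anterior homeobox genes otx1.L (-2.52 ± 0.12) and otx2.L (-1.72 ± 0.09) fell. So did the cement gland genes agr2.L (-1.97 ± 0.10), agr2.S (-1.55 ± 0.10) and ag1.S (-1.56 ± 0.079). Falls also occurred in hes7.1.L (-1.74 ± 0.10), the muscle regulator gene myf5.L (-1.72 ± 0.075), muc2l.L (-1.67 ± 0.089) and dmrta2.S (-1.65 ± 0.099). By the naming rule, the 12 largest rises and 12 largest falls were picked from genes called with the same direction in 3 of 3 females. They were called again after median centring.

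**Figure D1:**
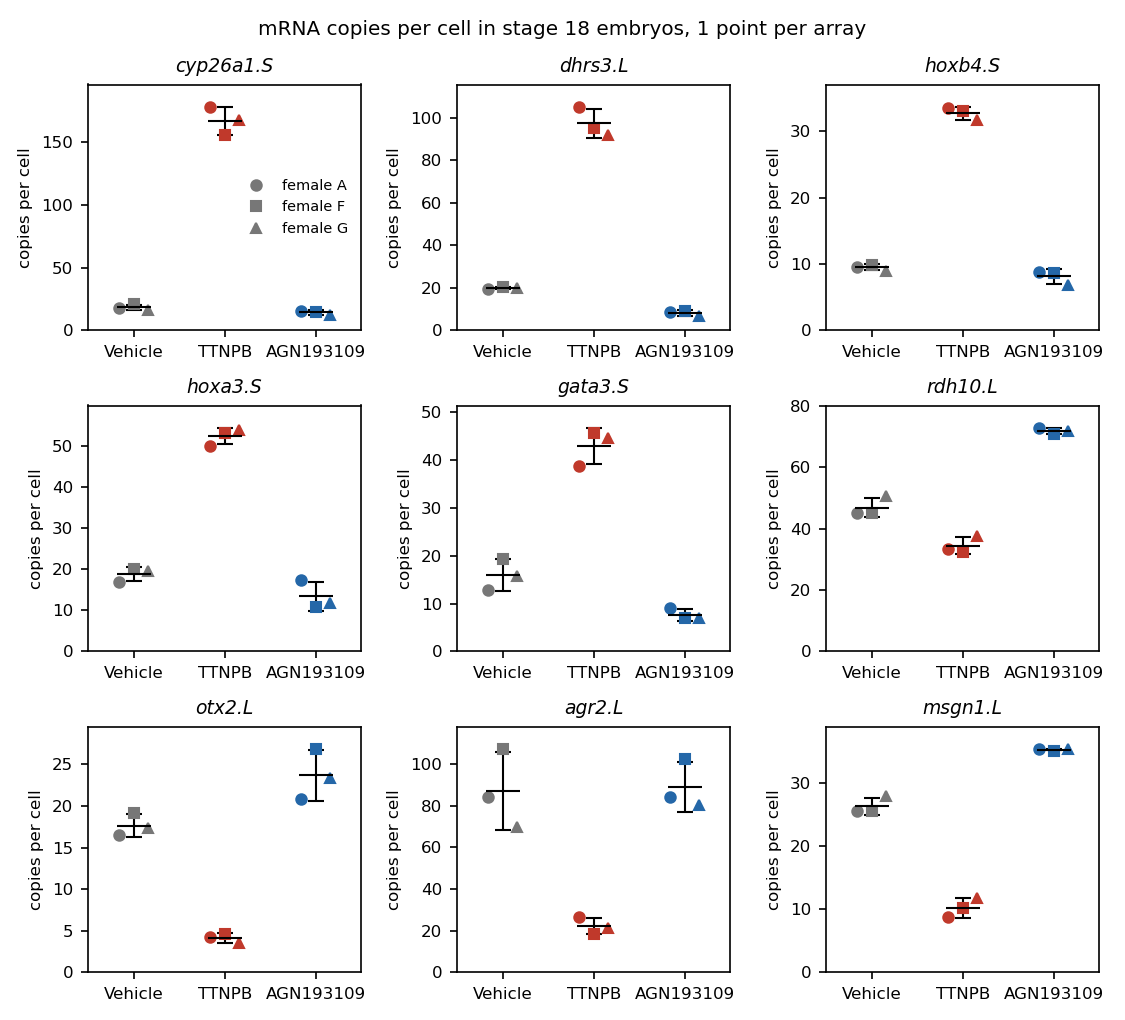
Copies per cell (vertical axes, linear from 0) of 9 genes, with 1 point per array, shapes for the 3 females and bars for the mean ± SD of each treatment. All TTNPB points lie above all vehicle points for cyp26a1.S, dhrs3.L, hoxb4.S, hoxa3.S and gata3.S, and below them for rdh10.L, otx2.L, agr2.L and msgn1.L.

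In the list of retinoic acid metabolism and transport, 4 of the 9 measured members rose, 2 fell and 3 were not called (4 and 3 adjusted over the list alone). Both cyp26a1 copies, dhrs3.L and the hydroxylase gene cyp26c1.S (0.63 ± 0.074) rose. The retinoic acid synthesis genes aldh1a2.L (-0.78 ± 0.09) and rdh10.L (-0.53 ± 0.066) fell, and crabp2.L was not called (-0.30). Camera's adjusted p was 6.94e-16 (adjusted p = 0.0604 with an estimated correlation). The list's test and mean log2 change as deposited were upward (0.81), but its median was -0.01. Of retinoid receptors and cofactors, 4 of the 14 measured members rose, 1 fell and 9 were not called (9 and 1 adjusted over the list alone). The genes nr2f5.S (0.52 ± 0.066), rxra.L (0.50 ± 0.078) and rara.L (0.47 ± 0.086) rose and rarg.S fell (-0.53 ± 0.068). The copies rxrb.L (0.15) and rxrb.S (0.15) were not called. The list's adjusted p in camera was 0.0370 (adjusted p = 0.801 with an estimated correlation).

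Of Hox genes of paralog groups 1 to 5, 7 of the 7 measured members rose, 0 fell and 0 were not called (7 and 0 adjusted over the list alone). The list median was 1.3. In copies per cell, hoxb4.S went from 9.51 ± 0.472 to 32.7 ± 0.962 and hoxb5.S from 2.94 ± 0.842 to 16.6 ± 2.51. By camera the adjusted p was 1.52e-25 (adjusted p = 0.0291 with an estimated correlation). Of groups 6 to 8, 1 of the 6 measured members rose, 0 fell and 5 were not called (2 and 0 adjusted over the list alone; 1 and 1 median centred), and camera's adjusted p was 0.751. The gene hoxc6.S was not called as deposited and was lower after median centring (-0.25 ± 0.073, adjusted p = 0.0364). Of groups 9 to 13, 1 of the 6 measured members rose, 3 fell and 2 were not called (1 and 4 adjusted over the list alone). The genes hoxc10.L (-0.79 ± 0.10) and hoxd10.L (-0.73 ± 0.088) fell, hoxb9 rose (0.45 ± 0.07) and hoxd13.S was not called (-0.21). In camera this list had an adjusted p of 0.00404 (adjusted p = 0.801 with an estimated correlation). Of hindbrain genes and Hox cofactors, 9 of the 14 measured members rose, 3 fell and 2 were not called (10 and 3 adjusted over the list alone). The cofactor genes meis3.S (0.83 ± 0.07) and meis3.L (0.43 ± 0.075) and tshz3.L (0.77 ± 0.11) rose. The ephrin receptor genes epha4.L (-0.76 ± 0.086) and epha2.L (-0.69 ± 0.064) fell. Camera's adjusted p was 0.00294 (adjusted p = 0.801 with an estimated correlation).

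Of the forebrain and eye list, 1 of the 26 measured members rose, 19 fell and 6 were not called (2 and 20 adjusted over the list alone). The eye field genes rax.S (-1.44 ± 0.089) and six3.L (-0.71 ± 0.081) fell, as did otx2.S (-1.14 ± 0.088), and six3.S was not called (0.19). The called rise of tbx3.L was lost after median centring (adjusted p = 0.0904). The list's adjusted p in camera was 4.81e-42 (adjusted p = 0.0291 with an estimated correlation). Of the cement gland and hatching gland list, 0 of the 10 measured members rose, 8 fell and 2 were not called (0 and 8 adjusted over the list alone). Its median was -1.34, and agr2.L went from 87.1 ± 18.9 to 22.2 ± 3.97 copies per cell. By camera the adjusted p was 4.09e-74 (adjusted p = 0.00613 with an estimated correlation). Of the midbrain list, 3 of the 11 measured members rose, 3 fell and 5 were not called (4 and 5 adjusted over the list alone; 3 and 5 median centred). The engrailed genes en2.S (-1.19 ± 0.11) and en2.L (-1.0 ± 0.13) fell, and fgf8.L (0.46 ± 0.068) and irx3.L (0.31 ± 0.082) rose. In camera this list had an adjusted p of 0.0330 (adjusted p = 0.801 with an estimated correlation). The call was lost after median centring (adjusted p = 0.229) or quantile normalization (0.328), with a filter at the 50th percentile (0.954) and with numbered gene copies as members (0.275). As deposited, the midbrain median was 0.07 and the mean -0.13, with a downward test.

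Of the neural crest list, 5 of the 35 measured members rose, 7 fell and 23 were not called (6 and 10 adjusted over the list alone; 3 and 11 median centred). The crest regulator snai2.L (-1.12 ± 0.098) and zic5.S (-1.0 ± 0.086) fell, and kctd15.L (0.41 ± 0.083) and c3.L (0.36 ± 0.07) rose. Camera's adjusted p was 4.55e-04 (adjusted p = 0.801 with an estimated correlation). Of primary neurogenesis and neurons, 15 of the 33 measured members rose, 0 fell and 18 were not called (16 and 0 adjusted over the list alone; 11 and 2 median centred). The neuronal filament gene prph.L went from 39.6 ± 2.01 to 90.4 ± 11 copies per cell (1.03 ± 0.069). The copy prph.S (0.73 ± 0.1) and the proneural gene neurog2.S (0.43 ± 0.09) rose too. The gene tubb2b.S was not called (0.05), and the rise of myt1.S was lost after median centring (adjusted p = 0.0569). The list's adjusted p in camera was 2.55e-04 (adjusted p = 0.801 with an estimated correlation). Of notochord and floor plate, 3 of the 18 measured members rose, 4 fell and 11 were not called (6 and 6 adjusted over the list alone; 2 and 8 median centred). Falls were those of foxd4l1.1.S (-1.06 ± 0.078) and sox9.S (-0.94 ± 0.072), and rises those of hhip.L (0.47 ± 0.11) and col2a1.S (0.38 ± 0.075). By camera the adjusted p was 0.0106 (adjusted p = 0.801 with an estimated correlation).

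Of multiciliated cells and ionocytes, 10 of the 26 measured members rose, 1 fell and 15 were not called (14 and 1 adjusted over the list alone). The proton pump gene atp6v0d2.L (0.76 ± 0.076) and the anion exchanger gene slc4a1.L (0.59 ± 0.091) rose, and foxn4.S fell (-0.53 ± 0.074). In camera this list had an adjusted p of 0.00182 (adjusted p = 0.801 with an estimated correlation). Of the pronephros list, 6 of the 15 measured members rose, 1 fell and 8 were not called (7 and 1 adjusted over the list alone; 4 and 2 median centred). There gata3.S and hey1.S (0.47 ± 0.086) rose and sall3.L fell (-0.46 ± 0.068). Camera's adjusted p was 0.0461 (adjusted p = 0.801 with an estimated correlation). With all probe sets of a gene the adjusted p was 0.947 and the direction turned. Of the FGF pathway, 9 of the 22 measured members rose, 1 fell and 12 were not called (11 and 1 adjusted over the list alone; 7 and 3 median centred). There dusp6.L and the repressor gene erf.S (0.51 ± 0.069) rose and egr1.L fell (-0.51 ± 0.11). The list's adjusted p in camera was 0.0102 (adjusted p = 0.801 with an estimated correlation).

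The list of caudal progenitors and presomitic mesoderm had 8 up and 9 down of 24 (8 and 10 adjusted over the list alone), and camera's adjusted p was 0.202. This list also holds both cyp26a1 copies. Its mean log2 change as deposited was 0.20 and its median 0.01, and relative to the array median its median was -0.10. The mesoderm gene msgn1.L fell from 26.3 ± 1.37 to 10.2 ± 1.54 copies per cell (-1.30 ± 0.077). The genes vegt.L (-0.87 ± 0.10) and tbxt.S (-0.80 ± 0.082) fell and wnt3a.S rose (0.32 ± 0.082). The rise of cdx4.L was lost after median centring (adjusted p = 0.0507). Of the lists from here on, camera called none as deposited, and the calls that it made under alternatives follow them. Somites had 3 up and 2 down of 14 (4 and 2 adjusted over the list alone; 2 and 4 median centred), with mespa.S up (0.38 ± 0.075). Skeletal muscle had 9 up and 1 down of 38 (9 and 2 adjusted over the list alone; 2 and 7 median centred), with pgam2.L up (0.72 ± 0.094). In muscle, myod1.S was not called as deposited and was lower after median centring (-0.33 ± 0.068, adjusted p = 0.00399). Heart had 6 up and 1 down of 17 (8 and 2 adjusted over the list alone; 3 and 3 median centred), with hand2.S up (0.84 ± 0.11) and nkx2-5.S down (-0.63 ± 0.094). Blood and vessels had 4 up and 4 down of 16 (5 and 7 adjusted over the list alone; 4 and 7 median centred), with lmo2.S down (-0.64 ± 0.067). Endoderm had 8 up and 1 down of 18 (10 and 1 adjusted over the list alone), with gata5.L up (0.43 ± 0.082) and frzb.L down (-0.85 ± 0.077). The Wnt pathway had 11 up and 3 down of 37 (15 and 3 adjusted over the list alone; 7 and 5 median centred), with wnt11.S (1.04 ± 0.086) and sfrp2.S (0.96 ± 0.074) up and wnt2b.L down (-1.05 ± 0.12). The BMP pathway had 3 up and 3 down of 34 (7 and 5 adjusted over the list alone; 2 and 7 median centred), with the inhibitor gene fst.L up (0.94 ± 0.076) and szl.L down (-0.73 ± 0.088).

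Epidermis had 9 up and 4 down of 37 (12 and 4 adjusted over the list alone; 4 and 4 median centred), with krt19.S down (-1.32 ± 0.086). Neural plate progenitors had 7 up and 5 down of 29 (10 and 6 adjusted over the list alone; 2 and 7 median centred), with zic2.S down (-0.74 ± 0.078). Placodes had 3 up and 2 down of 12 (3 and 2 adjusted over the list alone; 2 and 3 median centred), with foxi1.L up (0.28 ± 0.068). The cell cycle list had 8 up and 1 down of 67 (8 and 1 adjusted over the list alone; 3 and 7 median centred). Stress and apoptosis had 4 up and 1 down of 22 (5 and 1 adjusted over the list alone; 3 and 2 median centred), and the Notch pathway 2 up and 0 down of 13 (2 and 0 adjusted over the list alone; 2 and 2 median centred). Housekeeping references had 1 up and 1 down of 21 (4 and 1 adjusted over the list alone; 0 and 2 median centred), and ribosomal proteins 1 up and 1 down of 72 (0 and 0 adjusted over the list alone; 0 and 1 median centred).

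Camera called 9 of the 17 lists not called as deposited under some alternative, each in the direction of its deposited test. After median centring it called endoderm upward (adjusted p = 0.0268) and the BMP pathway downward (0.0192). With an estimated correlation as well, the adjusted p was 0.410 for endoderm and 0.127 for BMP. Endoderm was also called after quantile normalization (0.0155) and without female G (0.0448) or its Vehicle array (0.0303). The BMP pathway was also called after quantile normalization (0.0226), with the smaller pseudocount (0.0394), with no filter (0.0353) and with no replicate block (0.0133). It was called without female F or G, the Vehicle array of A or F or the TTNPB array of F or G (adjusted p from 0.00630 to 0.0403). Caudal progenitors were called upward with the larger pseudocount (0.0412), a filter at the 50th percentile (0.00146) and all probe sets of a gene (0.00388). They were also called without female A, the Vehicle array of G, the TTNPB array of A or any 1 AGN193109 array (adjusted p from 0.00825 to 0.0364). Both cyp26a1 copies, with their large rises, belong to the caudal list, which was not tested without them. These calls therefore do not show a rise of caudal genes in general. Neural plate progenitors were called downward with numbered copies as members (0.0305), and without female F (0.0457), its TTNPB array (0.0279) or the Vehicle array of A (0.0260). In 1 alternative each, camera called Notch downward (numbered copies, 0.0259), placodes downward (all probe sets of a gene, 0.00275) and heart upward (a filter at the 50th percentile, 0.0388). Likewise skeletal muscle was called downward without the Vehicle array of A (0.0260) and blood and vessels without the TTNPB array of F (0.0286). As deposited with an estimated correlation, the adjusted p of these 9 lists was 0.878 for endoderm, 0.937 for BMP and neural plate progenitors and 0.953 for the other 6.

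**Figure D2:**
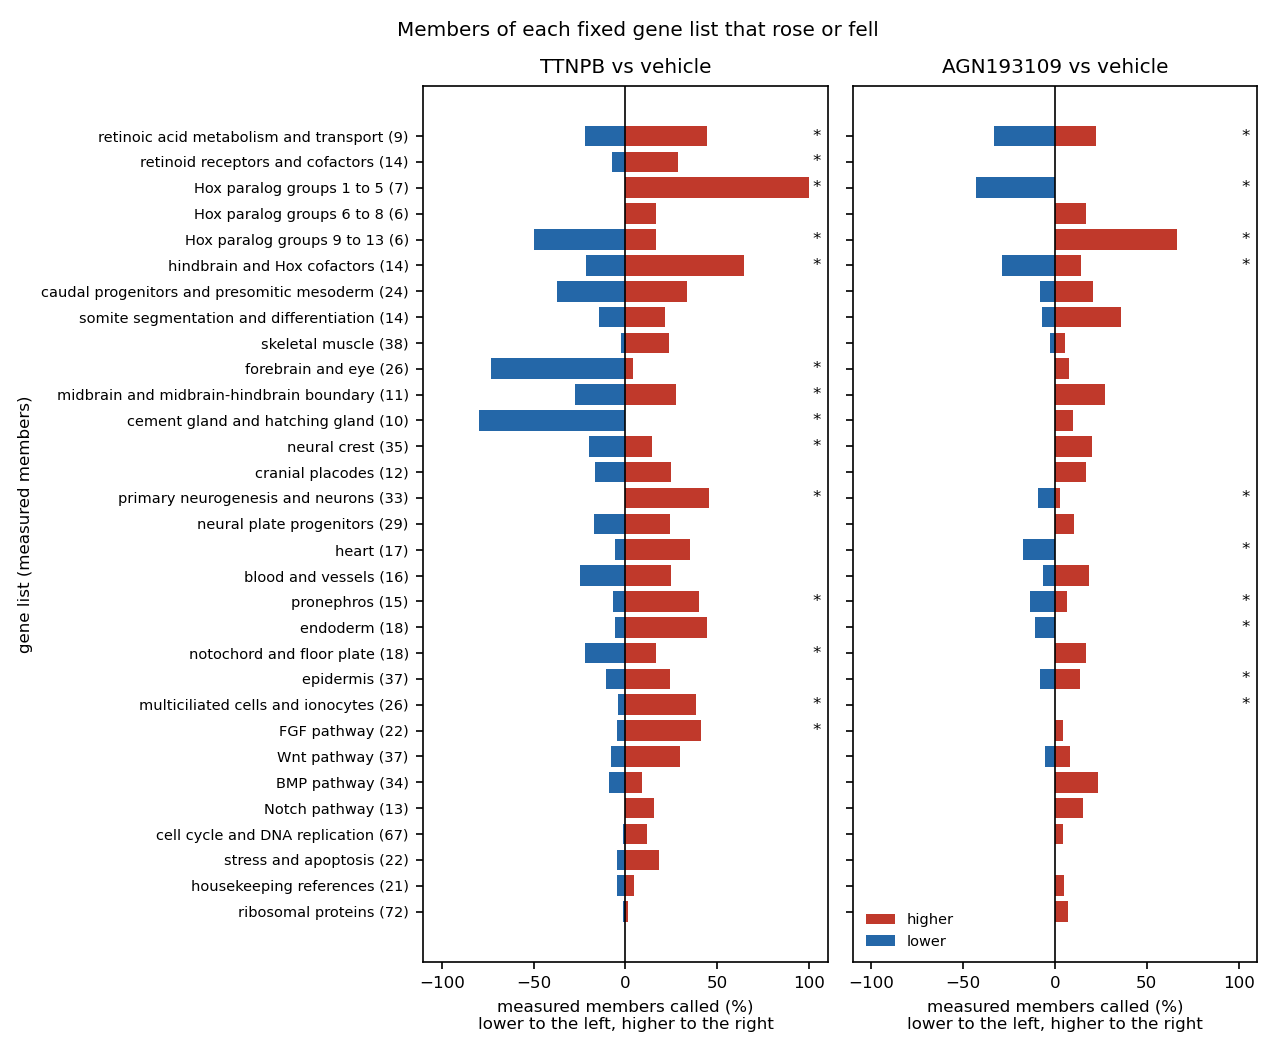
Share of the measured members of each of the 31 fixed gene lists that rose (to the right) or fell (to the left), in percent, for each ligand against vehicle as deposited, with asterisks for lists called by camera at its preset correlation. Under TTNPB all 7 Hox genes of groups 1 to 5 rose and 8 of 10 cement gland and hatching gland genes fell.

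In all, limma called 1333 probe sets under TTNPB, 1078 up and 255 down (80.9% up). Of these, 1267 moved the same way in all 3 females. After median centring 1185 were called, 561 up and 624 down (47.3% up), and 815 were shared with the same direction. After quantile normalization 1225 were called, 621 up and 604 down. With no replicate block 455 were called, and with each probe set's own variance 89. The count was 608 without female A, 597 without female G, 761 without the Vehicle array of A and 772 without that of G. It was 768 without the TTNPB array of A and 746 without that of G. Without female F camera's call was lost for retinoic acid metabolism (adjusted p = 0.130), retinoid receptors (0.105), hindbrain (0.105), midbrain (0.0767), pronephros (0.453) and the FGF pathway (0.105). These 6 calls were also lost without the TTNPB array of F, with adjusted p-values from 0.0539 to 0.313. Without the Vehicle array of F 4 of them were lost, retinoid receptors (0.0973), midbrain (0.0801), pronephros (0.175) and FGF (0.0657). Without the TTNPB array of G retinoid receptors (0.0547) and pronephros (0.0576) were lost, and notochord (0.0545) without that of A. A filter at the 50th percentile ended the calls of Hox groups 9 to 13 (0.382), retinoid receptors (0.135) and pronephros (0.120). Quantile normalization ended those of notochord (0.0550) and pronephros (0.0627). The notochord call was also lost with no filter (0.0559), and that of pronephros with the smaller pseudocount (0.0549) and no replicate block (0.0675).

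The second comparison asked what differs when signalling through these receptors is blocked. Of the 136 probe sets that AGN193109 lowered, 117 had risen under TTNPB. The astacin-like gene tll2l.L fell most, from 13.1 ± 1.27 to 3.04 ± 1.05 copies per cell (-1.65 ± 0.13). The homeobox gene gbx2.1.S fell (-1.31 ± 0.098). The gene dhrs3.L went from 19.9 ± 0.536 to 8.26 ± 1.27 copies per cell (-1.19 ± 0.07), and cyp26a1.L from 24.2 ± 3.84 to 11.5 ± 0.523 (-1.05 ± 0.08). The largest called rise was that of the G protein subunit gene gng13.S, from 1.80 ± 1.16 to 5.19 ± 0.604 copies per cell (0.76 ± 0.14).

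Other falls were those of lhx1.L, a LIM homeobox gene of the kidney primordium (-1.04 ± 0.084), sema3fl.S (-1.0 ± 0.14) and gata3.S (-0.98 ± 0.098). The fatty acid transporter gene slc27a2.L (-0.92 ± 0.093) and hand1.L, of the cardiac mesoderm (-0.92 ± 0.11), fell. So did ada.S, for adenosine deaminase (-0.91 ± 0.072), ak1.L, for adenylate kinase (-0.90 ± 0.068), and hao2.S, for hydroxyacid oxidase (-0.87 ± 0.095). Rises were those of the water channel gene aqp3.L (0.63 ± 0.086), tcaf1.L (0.61 ± 0.086), astl2e.2.L (0.48 ± 0.11) and gsto1.S (0.47 ± 0.08). The retinol dehydrogenase gene rdh10.L rose from 46.9 ± 3.16 to 71.8 ± 0.992 copies per cell (0.47 ± 0.066). So did klf10.L (0.47 ± 0.086), xa-1.L (0.44 ± 0.093), gdf3.S (0.44 ± 0.085) and klf17.1.S (0.44 ± 0.11), whose call was lost after quantile normalization (adjusted p = 0.0666). The called rises of astl3a.1.L and ntrk2.L were lost after median centring (adjusted p = 0.0804 and 0.0970).

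In retinoic acid metabolism and transport, 2 of the 9 measured members rose, 3 fell and 4 were not called (2 and 3 adjusted over the list alone). Both cyp26a1 copies (-0.45 ± 0.064 for cyp26a1.S) and dhrs3.L fell, and rdh10.L and aldh1a2.L (0.36 ± 0.09) rose, each opposite to its change under TTNPB. By camera the adjusted p was 1.37e-05 (adjusted p = 0.706 with an estimated correlation). Of Hox groups 1 to 5, 0 of the 7 measured members rose, 3 fell and 4 were not called (0 and 3 adjusted over the list alone). The genes hoxc5.L (-0.64 ± 0.12), hoxb5.S (-0.54) and hoxa3.S (-0.58 ± 0.10; lower in 2 of 3 females) fell. The means of hoxb5.S, 2.94 copies per cell under vehicle and 1.58 under AGN193109, lay below the 4.00 copies per cell of the filter. The gene hoxb4.S was not called as deposited and was lower after median centring (-0.31 ± 0.071, adjusted p = 0.0271). In camera this list had an adjusted p of 4.06e-08 (adjusted p = 0.641 with an estimated correlation). Of groups 9 to 13, 4 of the 6 measured members rose, 0 fell and 2 were not called (5 and 0 adjusted over the list alone). After median centring 2 and 0 were called, higher first. Both rises were lost after quantile normalization, hoxc10.L (0.42 ± 0.10, adjusted p = 0.0583) and hoxa11.S (0.41 ± 0.10, adjusted p = 0.0756). Camera's adjusted p was 0.0123 (adjusted p = 0.740 with an estimated correlation). Groups 6 to 8 had 1 up and 0 down of 6 (2 and 0 adjusted over the list alone; 0 and 0 median centred, 2 and 0 unadjusted), and the rise of hoxc6.S was lost after median centring (adjusted p = 0.295).

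Of hindbrain genes and Hox cofactors, 2 of the 14 measured members rose, 4 fell and 8 were not called (3 and 4 adjusted over the list alone; 0 and 6 median centred). Falls were those of meis3.L (-0.55 ± 0.075) and tshz3.L (-0.62 ± 0.11). The list's adjusted p in camera was 6.25e-05 (adjusted p = 0.740 with an estimated correlation). Of neurogenesis, 1 of the 33 measured members rose, 3 fell and 29 were not called (1 and 3 adjusted over the list alone; 0 and 3 median centred), with falls of lhx1.L and prph.L (-0.57 ± 0.069). By camera the adjusted p was 1.74e-05 (adjusted p = 0.740 with an estimated correlation). Of heart, 0 of the 17 measured members rose, 3 fell and 14 were not called (5 and 5 adjusted over the list alone). The genes hand1.L, gata5.L (-0.69 ± 0.082) and gata6.L (-0.41 ± 0.081) fell, and nkx2-5.S was not called (0.18). In camera this list had an adjusted p of 9.44e-06 (adjusted p = 0.740 with an estimated correlation). Of endoderm, 0 of the 18 measured members rose, 2 fell and 16 were not called (0 and 2 adjusted over the list alone), the falls again being gata5.L and gata6.L. Camera's adjusted p was 3.80e-04 (adjusted p = 0.740 with an estimated correlation). Of the pronephros list, 1 of the 15 measured members rose, 2 fell and 12 were not called (1 and 2 adjusted over the list alone; 0 and 2 median centred), with lhx1.L and gata3.S down. The list's adjusted p in camera was 2.86e-04 (adjusted p = 0.740 with an estimated correlation).

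Of epidermis, 5 of the 37 measured members rose, 3 fell and 29 were not called (8 and 3 adjusted over the list alone; 0 and 4 median centred). There krt12.4.S fell (-0.41 ± 0.10), and the rise of krt19.S was lost after median centring (adjusted p = 0.155). By camera the adjusted p was 0.0334 (adjusted p = 0.984 with an estimated correlation). Of multiciliated cells and ionocytes, 0 of the 26 measured members rose, 0 fell and 26 were not called in limma (0 and 0 adjusted over the list alone; 0 and 1 median centred; 1 up and 2 down at an unadjusted p below 0.05). In camera this list had an adjusted p of 6.47e-04 (adjusted p = 0.884 with an estimated correlation). Fry gave adjusted p-values of 0.482 for epidermis and 0.940 for multiciliated cells, with the direction turned. Camera's test was downward for 5 lists whose median or mean as deposited was not. The medians were 0.00 for neurogenesis, 0.00 for endoderm, 0.07 for pronephros, 0.06 for epidermis and -0.03 for multiciliated cells. The means were -0.01, -0.01, -0.05, 0.04 and 0.00 in that order. Camera sets a list against the other tested genes, while fry tests it against no change. Relative to the array median, the list medians were -0.13, -0.12, -0.06, -0.07 and -0.16 in the same order.

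Camera called none of the other lists under AGN193109 as deposited. Forebrain and eye had 2 up and 0 down of 26 (6 and 0 adjusted over the list alone; 0 and 0 median centred, 6 and 2 unadjusted), and the rise of otx2.L was lost after median centring (adjusted p = 0.203). The genes rax.S (0.06) and six3.L (0.05) were not called. Cement gland and hatching gland had 1 up and 0 down of 10 (3 and 0 adjusted over the list alone; 0 and 0 median centred, 2 and 0 unadjusted), and agr2.L was not called (-0.08). The midbrain had 3 up and 0 down of 11 (5 and 0 adjusted over the list alone; 0 and 0 median centred, 4 and 1 unadjusted). Neural crest had 7 up and 0 down of 35 (10 and 1 adjusted over the list alone; 1 and 1 median centred), with hes4.S up (0.30 ± 0.071). Neural plate progenitors had 3 up and 0 down of 29 (4 and 0 adjusted over the list alone), with foxd4l1.1.S up (0.34 ± 0.078). Caudal progenitors had 5 up and 2 down of 24 (10 and 2 adjusted over the list alone; 2 and 3 median centred), with tbx6r.L up (0.42 ± 0.071). Somites had 5 up and 1 down of 14 (5 and 1 adjusted over the list alone; 1 and 1 median centred), with mespa.L down (-0.53 ± 0.11). The Wnt pathway had 3 up and 2 down of 37 (8 and 2 adjusted over the list alone; 0 and 3 median centred), with sfrp2.S (-0.60 ± 0.074) and ror2.L (-0.43 ± 0.067) down. Blood and vessels had 3 up and 1 down of 16 (4 and 1 adjusted over the list alone; 1 and 2 median centred), with aplnr.L up (0.35 ± 0.074).

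The BMP pathway had 8 up and 0 down of 34 (15 and 1 adjusted over the list alone; 0 and 3 median centred). Skeletal muscle had 2 up and 1 down of 38 (3 and 1 adjusted over the list alone; 0 and 3 median centred), and notochord and floor plate 3 up and 0 down of 18 (5 and 0 adjusted over the list alone; 1 and 1 median centred). Placodes had 2 up and 0 down of 12 (3 and 0 adjusted over the list alone; 0 and 0 median centred, 3 and 3 unadjusted), the FGF pathway 1 up and 0 down of 22 (3 and 0 adjusted over the list alone; 0 and 0 median centred, 2 and 4 unadjusted) and the Notch pathway 2 up and 0 down of 13 (2 and 0 adjusted over the list alone). The cell cycle had 3 up and 0 down of 67 (3 and 0 adjusted over the list alone; 0 and 0 median centred, 4 and 3 unadjusted). Housekeeping references had 1 up and 0 down of 21 (1 and 0 adjusted over the list alone; 0 and 0 median centred, 1 and 1 unadjusted), and ribosomal proteins 5 up and 0 down of 72 (5 and 0 adjusted over the list alone; 0 and 0 median centred, 2 and 0 unadjusted). Limma called 0 up and 0 down of 14 (0 and 0 adjusted over the list alone; 0 and 2 median centred) for retinoid receptors, where 4 were higher and 2 lower at an unadjusted p below 0.05. For stress and apoptosis limma called 0 up and 0 down of 22 (0 and 0 adjusted over the list alone; 0 and 1 median centred), where 6 were higher and 1 lower at an unadjusted p below 0.05.

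Of the 21 lists not called as deposited, camera called 7 under some alternative, each in the direction of its deposited test. After median centring it called 3 upward, forebrain and eye (adjusted p = 0.0117), the midbrain (0.0117) and the BMP pathway (0.0302), whose called members were then falls. With an estimated correlation as well, the adjusted p of each was 0.215. Forebrain and midbrain were also called after quantile normalization (0.0472 and 0.0331), with the larger pseudocount (0.0332 and 0.0390) and with no replicate block (0.0304 and 0.0162). Both were called without female G, its TTNPB array or its AGN193109 array, with adjusted p from 0.0195 to 0.0368 for forebrain and from 0.0281 to 0.0368 for midbrain. The midbrain was called too with no filter (0.00690) and without the Vehicle array of F (0.0263). The BMP pathway was called without female G (0.0195) or its AGN193109 array (0.0113). Cement gland and hatching gland were called upward with the larger pseudocount (0.0332), with all probe sets of a gene (0.0407) and without female G (0.0457) or its TTNPB array (0.0368). Skeletal muscle was called downward without female A (6.26e-04), its Vehicle array (0.0256) or its AGN193109 array (0.00284). Housekeeping references were called downward without female G (0.0211) or its AGN193109 array (0.0131). Ribosomal proteins were called upward after quantile normalization (0.00198) and without the Vehicle array of F (0.00963), the TTNPB array of A (8.42e-04) or the AGN193109 array of F (0.00102). As deposited with an estimated correlation, the adjusted p was 0.740 for cement gland and hatching gland and 0.984 for the other 6.

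In all, limma called 647 probe sets under AGN193109, 511 up and 136 down (79.0% up). Of these, 619 moved the same way in all 3 females. After median centring 288 were called, 47 up and 241 down (16.3% up), and 181 were shared with the same direction. After quantile normalization 290 were called, 56 up and 234 down. With no replicate block 34 were called, 5 up and 29 down, and with each probe set's own variance 1. The count was 164 without female A (61 up and 103 down), 361 without F, 180 without G, 237 without the Vehicle array of A (113 and 124) and 179 without that of G. It was 197 without the AGN193109 array of A (97 and 100) and 161 without that of F. Camera's call for Hox groups 9 to 13 was lost without female A (adjusted p = 0.173), without F (0.127), without the AGN193109 array of A (0.146) or the TTNPB array of F (0.0775), and with a filter at the 50th percentile (0.507). The epidermis call was lost without female A (0.130) or F (0.0729) and without the AGN193109 array of A (0.158) or F (0.255) or the TTNPB array of A (0.0511). It was also lost after quantile normalization (0.142), with no filter (0.0993) and with numbered copies as members (0.153). The endoderm call was lost without female G (0.0527).

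The ligands were compared directly at the same dose and time. Levels were higher under TTNPB for cyp26a1.L (log2 difference 3.60 ± 0.08), cyp26a1.S (3.36 ± 0.064), dhrs3.L (3.24 ± 0.07) and pik3r5.S (2.26 ± 0.11). The same held for hoxb5.S (2.25 ± 0.12), tll2l.L (2.23 ± 0.13), gata3.S (2.18 ± 0.098), gbx2.1.S (2.15 ± 0.098) and hao2.S (1.89 ± 0.095). Levels were lower for astl3a.1.L (-3.59 ± 0.16), xa-1.L (-3.30 ± 0.093), crisp1.5.S (-3.11 ± 0.095) and otx1.L (-2.81 ± 0.12). They were also lower for gdf3.S (-1.98 ± 0.085), otx2.L (-1.97 ± 0.09), aqp3.L (-1.84 ± 0.086) and myf5.L (-1.79 ± 0.075). The largest differences were picked from genes called with the same direction in 3 of 3 females. Each of these genes was called again after median centring. The receptor gene rara.L was higher (0.91 ± 0.086) and rarg.S lower (-0.60 ± 0.068). The synthesis genes aldh1a2.L (-1.15 ± 0.09) and rdh10.L (-1.0 ± 0.066) were lower. The test was not passed by rxrb.L (0.19 ± 0.084), rxrb.S (0.10 ± 0.079), wnt3a.S (0.13 ± 0.082), crabp2.L (-0.10 ± 0.095) and six3.S (0.03 ± 0.14), which does not show that the ligands act alike on them.

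Camera called 16 of the 31 lists between the ligands. Higher under TTNPB were Hox groups 1 to 5 with 7 up and 0 down of 7 (7 and 0 adjusted over the list alone) and retinoic acid metabolism with 4 up and 2 down of 9 (4 and 4 adjusted over the list alone). In the latter the median was -0.11 and the mean 0.91 as deposited, with an upward test. Hindbrain genes had 9 up and 4 down of 14 (9 and 4 adjusted over the list alone). Neurogenesis had 17 up and 1 down of 33 (20 and 3 adjusted over the list alone), with prph.L at 1.59. Heart had 8 up and 4 down of 17 (8 and 5 adjusted over the list alone), with hand1.L at 1.37. Pronephros had 6 up and 3 down of 15 (8 and 3 adjusted over the list alone). Endoderm had 8 up and 3 down of 18 (9 and 3 adjusted over the list alone; 10 and 2 median centred), with gata5.L at 1.12. Multiciliated cells had 10 up and 1 down of 26 (12 and 1 adjusted over the list alone). The FGF pathway had 10 up and 5 down of 22 (10 and 7 adjusted over the list alone), with dusp6.L at 1.52. Lower were cement gland and hatching gland with 0 up and 9 down of 10 (0 and 10 adjusted over the list alone), and forebrain and eye with 0 up and 21 down of 26 (2 and 21 adjusted over the list alone). Hox groups 9 to 13 had 1 up and 5 down of 6 (1 and 5 adjusted over the list alone), and the midbrain 2 up and 6 down of 11 (2 and 6 adjusted over the list alone). Neural crest had 4 up and 17 down of 35 (6 and 18 adjusted over the list alone), with snai2.L at -1.38. Notochord and floor plate had 3 up and 9 down of 18 (5 and 10 adjusted over the list alone). The BMP pathway had 4 up and 15 down of 34 (5 and 19 adjusted over the list alone), with szl.L at -1.05. Camera's adjusted p-values ran from 2.57e-45 for cement gland and hatching gland to 0.0417 for the FGF pathway. With an estimated correlation the adjusted p = 0.0164 for cement gland and hatching gland and 0.0461 for Hox groups 1 to 5. For the other 14 the adjusted p with an estimated correlation ran from 0.0607 for forebrain and eye to 0.819 for the FGF and BMP pathways.

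The other 15 lists were not called by camera as deposited. Caudal progenitors had 6 up and 10 down of 24 (6 and 11 adjusted over the list alone), with msgn1.L at -1.57 and tbxt.S at -0.94. Skeletal muscle had 9 up and 9 down of 38 (10 and 14 adjusted over the list alone; 7 and 11 median centred). Epidermis had 11 up and 8 down of 37 (12 and 8 adjusted over the list alone), with krt19.S at -1.58. The Wnt pathway had 8 up and 6 down of 37 (9 and 8 adjusted over the list alone), and blood and vessels 4 up and 7 down of 16 (4 and 9 adjusted over the list alone). Neural plate progenitors had 3 up and 9 down of 29 (4 and 11 adjusted over the list alone), and somites 3 up and 6 down of 14 (3 and 7 adjusted over the list alone). The Notch pathway had 2 up and 3 down of 13 (2 and 4 adjusted over the list alone), and the cell cycle 5 up and 5 down of 67 (5 and 5 adjusted over the list alone; 3 and 7 median centred). Stress and apoptosis had 3 up and 4 down of 22 (3 and 4 adjusted over the list alone), and placodes 2 up and 3 down of 12 (3 and 3 adjusted over the list alone). Retinoid receptors had 3 up and 1 down of 14 (3 and 1 adjusted over the list alone), and housekeeping references 1 up and 1 down of 21 (1 and 1 adjusted over the list alone; 0 and 1 median centred). Ribosomal proteins had 0 up and 4 down of 72 (0 and 1 adjusted over the list alone), and Hox groups 6 to 8 had 0 up and 1 down of 6 (0 and 1 adjusted over the list alone).

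Of these 15 lists, camera called 9 under some alternative, each in the direction of its deposited test. Retinoid receptors were called higher under TTNPB after median centring (adjusted p = 0.0305; 0.166 with an estimated correlation as well), after quantile normalization (0.0378) and with no replicate block (0.0212). With numbered copies as members, Wnt was called higher (0.0302), and somites (0.0367), Notch (0.0194) and neural plate progenitors (0.0190) lower. With all probe sets of a gene, caudal progenitors (0.0293) and epidermis (0.0214) were called higher, and placodes (0.0212) and neural plate progenitors (0.0473) lower. Caudal progenitors were also called with a filter at the 50th percentile (0.00850) and without the Vehicle array of G (0.0423) or the AGN193109 array of F (0.0156). As deposited, the median of this list was -0.05 and its mean 0.09, with both cyp26a1 copies among its members. Ribosomal proteins were called lower after quantile normalization (0.0349) and without female F (0.0285) or the TTNPB array of A (0.0256). As deposited with an estimated correlation, the adjusted p was 0.765 for retinoid receptors, 0.905 for neural plate progenitors and 0.961 for the other 7.

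Limma called 1834 probe sets between the ligands, 877 higher and 957 lower under TTNPB (47.8% higher). Of these, 1762 had the same direction in all 3 females, and 1727 were called again with that direction after median centring. With no replicate block 857 were called, and with each probe set's own variance 450. The count was 1161 without female G and 1170 without the AGN193109 array of F. More were higher than lower with no replicate block (478 and 379). The same held without female A (670 and 632) or F (773 and 502), and without the Vehicle array of G (794 and 790), the TTNPB array of F (902 and 516) or the AGN193109 array of A (842 and 621) or F (638 and 532). It held too with no trend (783 and 761), array weights (1235 and 936), a threshold of 0.01 (695 and 636) and each probe set's own variance (239 and 211). After median centring it held with each probe set's own variance (520 and 496) and with no replicate block (629 and 507). Camera's call for the FGF pathway was lost after median centring (adjusted p = 0.0504) and quantile normalization (0.0604), with no replicate block (0.0517), and without female A (0.0538) or G (0.193). It was also lost without the TTNPB array of F (0.0554) or G (0.119) and without the AGN193109 array of A (0.0665) or G (0.132). The midbrain call was lost with numbered copies as members (0.734) and, like Hox groups 9 to 13 (0.331) and the BMP pathway (0.0681), with a filter at the 50th percentile (0.580). Quantile normalization ended the calls of retinoic acid metabolism (0.0863) and notochord (0.0582), and no filter those of heart (0.113) and notochord (0.0637). Without female A, BMP (0.124) and notochord (0.0869) were lost, as without its TTNPB array (0.0785 and 0.0554) or its AGN193109 array (0.0915 and 0.0659). Heart was lost without the TTNPB array of F (0.0773) and pronephros with all probe sets of a gene (0.313).

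Across the 11325 tested probe sets, which are not independent replicates, the log2 changes under the 2 ligands had a correlation of -0.338. Unchanged groups that shared the vehicle arrays gave 0.480 to 0.516 in 100 simulations, with noise independent between probe sets. The covariance was -0.0108 against a simulated 0.00575, a difference of -0.0165. The correlation was -0.220 without female F, -0.209 without the Vehicle array of F, -0.213 without that of G and -0.223 with no filter on low values. As deposited, 259 probe sets were called under both ligands. Of these, 117 rose under TTNPB and fell under AGN193109 (12.9 from independent lists), and 95 did the reverse (11.5). Another 46 rose under both (48.6), and 1 fell under both (3.06). After median centring 195 were called under both. Of these, 160 rose under TTNPB and fell under AGN193109 (11.9 from independent lists), and 29 did the reverse (2.59). Limma then called 0 higher under both (2.33; 69 at an unadjusted p below 0.05) and 6 lower under both (13.3). For these counts of calls the 3 vehicle arrays were too few to be split between the ligands. The noise that they share adds to the same-direction counts, which were not above those of independent lists. Of the 80 probe sets called under TTNPB with at least a 2-fold change as deposited, 74 had the opposite sign under AGN193109 relative to the array median. That sign was counted whether or not the AGN193109 change was called.

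**Figure D3:**
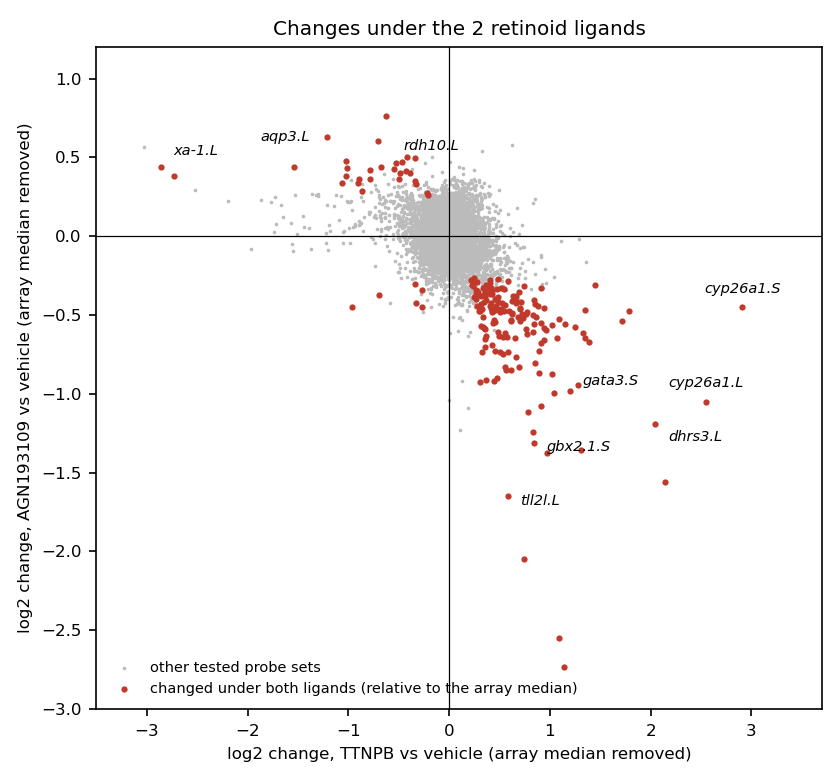
Log2 change under TTNPB (horizontal) and under AGN193109 (vertical) against vehicle for the 11325 tested probe sets, relative to the array median, with red points for the 195 called under both ligands after median centring. Of these, 160 lie at lower right and 29 at upper left.

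**Figure D4:**
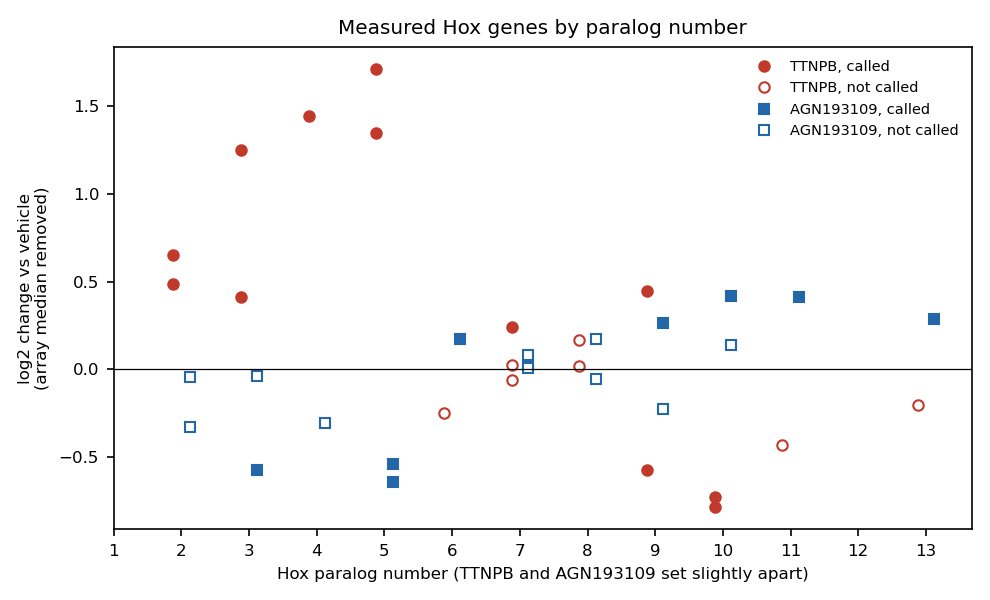
Log2 change against vehicle, relative to the array median, of the 19 measured Hox genes by paralog number under TTNPB (circles) and AGN193109 (squares), with filled symbols for genes called as deposited. All 7 genes of groups 1 to 5 rose under TTNPB, and of the filled squares above 0 hoxc10.L and hoxa11.S alone were called again after median centring.

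The clutches also differed. Between the 3 females 2534 probe sets differed (limma F test on the block, adjusted p below 0.05), and 2227 after median centring. The count was 1318 without the Vehicle array of G and 1436 without the AGN193109 array of F. The largest range was that of eps8l3.S, with 0.519 ± 0.210 copies per cell in the offspring of female A (mean ± SD over the 3 treatments, n = 3). It had 49.0 ± 1.1 in those of F and 50.9 ± 5.58 in those of G. The glutathione peroxidase gene gpx1.S had 21.8 ± 3.43, 5.65 ± 0.941 and 1.97 ± 0.551 copies per cell in the same order. The purine synthesis gene adsl.L had 4.39 ± 1.23, 17.3 ± 0.830 and 5.96 ± 0.430.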

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

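All tests of explanations in this part were chosen after the results were seen. The array carries control probe sets that took no part in the comparisons, and limma called 7 of the 120 under TTNPB and 7 under AGN193109 as deposited. Of these, 4 and 3 were called again after median centring, and they are described here. The 3 Gapd controls rose under TTNPB, with log2 changes as deposited of 0.57 (3 prime), 0.46 (5 prime) and 0.58 (middle), and fell under AGN193109, with -0.67, -0.68 and -0.55. Relative to the array median the directions were the same, with 0.46, 0.35 and 0.47 under TTNPB and -0.79, -0.80 and -0.68 under AGN193109. The control for pd2EGFP, a fluorescent protein sequence that is not from the frog, was lower under TTNPB by a log2 change of -0.56 (limma, adjusted p = 0.000326). Its level was 3.77 ± 0.438 copies per cell under vehicle and 1.78 ± 0.430 under TTNPB (SD, n = 3), both below the 4.00 copies per cell used as the filter.

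The Gapd pattern was set against degraded RNA, a factor shared by an array, and a response of the transcript. The 3 prime minus 5 prime difference changed between the ligands by 0.10 (SD 0.0900), while the 3 prime probe set changed by 1.24, which argues against degradation. The 9 actin controls changed between the ligands by a median of -0.0917 (SD 0.107), while the smallest Gapd change was 1.13, which argues against a shared factor. All 18 of 18 comparisons within a female had the direction of the pattern, as a response of the transcript needs. They are not independent: they come from 3 probe sets in 3 females, with each vehicle array used for both ligands. The probe sets were also picked as called under both ligands, which made this agreement likely beforehand. A response of the transcript remains a hypothesis, found and tested on the same arrays. Which transcript the controls detect is open, since limma did not call gapdh.L itself (0.11, adjusted p = 0.579 under TTNPB and 0.02, adjusted p = 0.901 under AGN193109, as deposited).

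Rises outnumbered falls under both ligands as deposited, except under AGN193109 with no replicate block (5 up and 29 down) or without female A (61 and 103), its Vehicle array (113 and 124) or its AGN193109 array (97 and 100), and with each probe set's own variance, where the 1 call was a fall. If 1 factor per array caused this, control probe sets would move as the tested ones did, by a median of 0.09 under TTNPB and 0.12 under AGN193109. The bacterial hybridization controls, which come from no embryo, had 0.13 (SD 0.0878) and 0.19 (SD 0.0740), but the actin controls had 0.00787 (SD 0.102) and 0.12 (SD 0.0754). The Bacillus spikes had 0.0394 (SD 0.0809) and -0.00122 (SD 0.0754), which decides nothing, since the authors set the scale of each array by them. A shared factor and more RNA per cell under the ligand both stay open: the summed copies were higher in 2 of 3 females under TTNPB and in 3 of 3 under AGN193109, and 3 females allow no exact p below 0.25. The hybridization controls cannot separate the 2 explanations. More RNA per cell would dilute the spikes that set the scale, and so raise controls added in equal amount to each array.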

How the results depend on the processing

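The alternatives with each probe set's own variance, those that combine 2 choices, and leaving out females for the sums or arrays for the differences between females were chosen after seeing the data. No named gene called as deposited turned its direction with median centring, quantile normalization, the other pseudocounts or filters, no replicate block, or a female or array left out. Of 107 named calls under TTNPB, 6 were lost with median centring and 23 with no replicate block. Of 70 under AGN193109, 28 and 55 were lost, and of 124 between the ligands 2 and 13. With no replicate block, against the pairing by female, the calls were 455, 34 and 857 (TTNPB, AGN193109, between the ligands), and with median centring as well 454, 74 and 1136. With each probe set's own variance they were 89, 1 and 450, and with median centring as well 282, 1 and 1016. With 1 probe set per gene, which tests fewer, they were 715, 331 and 1002. Array weights gave 3937 under TTNPB and 1459 under AGN193109, and a threshold of 0.01 gave 863 and 264. The p-values of the authors' deposited table, after Benjamini-Hochberg adjustment, gave 572 and 32. For AGN193109 alone, median centring gave 288, quantile normalization 290, no filter on low values 243, only the 6 arrays of the contrast 402, no trend 250 and a threshold of 0.1 gave 1086.

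Of 14, 10 and 16 lists called, camera with an estimated correlation called 3, 0 and 2 (4, 2 and 4 at an unadjusted p below 0.05). Fry called 6, 0 and 7 (12, 2 and 14), and median centring with an estimated correlation 4, 0 and 4 (10, 6 and 9). The pronephros list under TTNPB turned its direction with all probe sets of a gene (adjusted p = 0.947), as did epidermis (0.482) and multiciliated cells (0.940) under AGN193109 with fry. The correlation of the ligands was -0.366 with quantile normalization, -0.291 and -0.379 with pseudocounts at the 5th and 40th percentile, -0.223 with no filter and -0.408 with a filter at the 50th percentile. Where not stated, the cause was not tested.

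With a female or an array left out, the calls ranged from 597 to 1776 under TTNPB, from 161 to 967 under AGN193109 and from 1161 to 1948 between the ligands. Lists called ranged from 10 to 17, 8 to 14 and 13 to 17, and the correlation from -0.358 to -0.209. Log2 sums ranged from 0.04 to 0.16, 0.07 to 0.14 and -0.03 to 0.02, and probe sets differing between females from 1318 to 3120. Signal near the floor limits low genes, whose changes the pseudocount understates.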

Other observations

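The tests of hypotheses and of other splits in this part were chosen after the results were seen. The L and S copies of a gene could be compared in 791 pairs. Across these pairs their log2 changes had a correlation of 0.653 under TTNPB and 0.255 under AGN193109. Both copies were called in 45 pairs under TTNPB, 43 of them in the same direction. As deposited, 80.9% of all TTNPB calls were rises, which alone favours a shared direction. The response of the copies differed in 56 pairs under TTNPB and 14 under AGN193109 (limma, adjusted p below 0.05). Because the pseudocount understates changes of low genes, unequal levels of the copies can add to such differences, and this was not tested. For the annexin gene anxa2 the changes relative to the array median were 0.36 (L) and -0.65 (S) under TTNPB, a difference of 1.01 ± 0.0961 (SE; adjusted p = 0.000171). The eye gene rax had -0.50 and -1.44, six6 -1.39 and -0.48, and six3 -0.71 and 0.19. Under AGN193109, cyp26a1 had -1.05 and -0.45 (difference -0.60 ± 0.0983, adjusted p = 0.00689), and ak1 had -0.90 and 0.06.

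A hypothesis is that the response of Hox genes to TTNPB follows the paralog number. Over 19 measured Hox genes, which are not independent, Spearman's rho was -0.761 and Pearson's r -0.690 (permutation p of rho = 0.00029, 100000 resamples). Under AGN193109 rho was 0.737 and r 0.687 (permutation p = 0.00045). The gene hoxb9 rose under TTNPB and is an exception.

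The opposite changes under the 2 ligands were weighed against noise. With simulated noise that was independent between probe sets, shared vehicle arrays gave a correlation of at least 0.480, against -0.338 observed. Noise shared between probe sets was not simulated and could widen the simulated range, so 0.480 is no firm bound. In brighter probe sets the correlation was -0.408. This does not test noise near the detection limit, since simulated noise with shared vehicle arrays pushed the correlation above 0. Between a TTNPB change of 1 female and an AGN193109 change of another, which share no array, the highest of 6 correlations was -0.200. Within a female, where both changes share the vehicle array, the correlations were nearer to none, at -0.0520 (A), -0.0794 (F) and -0.0703 (G). These values are consistent with opposite responses of the same genes, as a hypothesis.

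For each comparison the 6 arrays were split into 3 and 3 in all 10 ways, with the female as a block. For TTNPB the real split called 1098 probe sets in limma and the highest other 137 (2346 and 1114 at an unadjusted p below 0.05). For AGN193109 these were 402 and 20 (2639 and 1895), and between the ligands 1891 and 0 (2916 and 504). In each, 1 of 10 splits reached the real count, and 10 splits are too few for a share under 0.05. Among the 4 splits that part all pairs, the highest other counts were 11, 8 and 0.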
